A study of Mus musculus with 12 samples.

How the data were processed

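Lung and liver of 3 tumor-bearing and 3 control mice were measured on Affymetrix mouse expression arrays, 1 array per tissue sample, 12 arrays in all, collected on day 7. The deposited values are log2 expression summaries per probe set that the authors made with GCRMA, which corrects background by probe sequence and normalizes by quantiles. The submitters' processing notes also name limma; the versions and settings of both are not given in the sources used here. The deposited log2 scale was checked on the values: every array had the same lowest value of 2.044. The number of arrays limits the precision. The labels name no scan dates or batches.

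Of 22626 probe sets, 20380 were listed with 1 gene symbol, 691 with several genes and 1555 were not listed, the latter groups being left out of the gene tests. The 12393 genes were each represented by the probe set with the highest mean over all 12 arrays. Genes with a value above 4 (log2) on at least 3 of the arrays fitted were tested. Within each tissue tumor-bearing and control arrays were compared with limma 3.58.1 (lmFit and eBayes, without trend or robust options) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The difference between tissues was tested as the interaction on all 12 arrays. Each adjusted p of a gene is from limma. The groups, comparisons, filter, gene lists, rule for named genes and most alternatives were chosen before the data were examined.

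Gene lists, 50 in number with 995 members of which 868 matched a probe set, were tested with limma's camera (inter-gene correlation preset at 0.01) when at least 5 members were tested, with adjustment over the lists of a tissue. Beside it stand camera with a correlation estimated from the residuals, and fry, which tests whether the genes of a list move on balance in one direction and compares the list with no other genes. For each list, members past the threshold were counted over all genes tested and adjusted over the list alone.

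Genes were named by rule. These were the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, for each list called the members with the largest absolute change among those past the threshold, or the 2 largest where no member passed, a fixed set of genes tied to the pre-metastatic niche, genes called in both tissues, and the 5 genes with the smallest p in each direction of the difference between tissues.

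Alternatives covered the filter, the choice of probe sets, further quantile normalization or median centring, eBayes options, array weights, all 12 arrays in 1 fit, the replicate number as a block, each array left out in turn and other thresholds. Chosen after seeing the data were leaving out the 2 lung arrays with hepatocyte transcripts, leaving out liver-enriched genes, setting values under 4 to 4 for the sizes of named genes in the difference between tissues, and list tests of the difference between tissues. The labels say that both tissues came from the same mice but not that a replicate number marks a mouse, so numbers were not used as pairs. Tested on simulated data with 200 changed genes, the tests recovered 63.5% in lung, 65.5% in liver and 51.5% in the difference between tissues at a log2 change of 1, and 90%, 85.5% and 85% at a log2 change of 2, with 3 to 9 false calls. The simulated noise was normal and independent between genes and arrays, with no lowest value, so these rates may not hold for the real arrays.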

Results

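RNA from lung and liver was measured on Affymetrix mouse expression arrays, 1 array per tissue sample, 7 days after injection of female NCR nude mice. Nude mice lack a working thymus and most mature T cells. The tumor-bearing mice carried an orthotopic tumor of 4T1 cells, a mouse mammary carcinoma line that spreads to lung and liver, and the control mice received phosphate-buffered saline (PBS). Each of the 4 groups (lung or liver, tumor-bearing or control) held 3 arrays, 12 in all. The sample titles call the tissues of the tumor-bearing mice pre-metastatic, so the comparisons ask what differs in these organs at day 7. The values are log2 GCRMA values, and the number of arrays limits the precision. Of the values of each array 26.7% to 28.5% lay within 0.05 of the shared lowest value of 2.044.

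The arrays carried the transcripts of their labelled tissues. Sftpc, a surfactant protein gene of alveolar type II cells, read 15.70 to 15.86 (log2) on the lung arrays and 2.24 to 6.54 on the liver arrays. Alb, the albumin gene of hepatocytes, read 16.05 to 16.20 on the liver arrays. On the lung arrays Alb read 14.39 in tumor replicate 1 and 14.65 in control replicate 3, against 8.96 to 11.08 on the other lung arrays, so 1 lung array of each group carried more hepatocyte transcripts than the rest. Arrays of the same group correlated at 0.989 to 0.996 over all probe sets.

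Granulocyte genes were far higher in the lungs of tumor-bearing mice than in control lungs. Ltf, which codes for the granule protein lactoferrin, averaged 8.88 ± 0.30 in tumor-bearing and 2.53 ± 0.53 in control mice (log2, SD, n = 3 each), at least 29.5-fold higher (limma adjusted p = 0.00186). Where all arrays of a group lay at or under the filter value of 4, such a fold is a lower bound against that value. Camp, the cathelicidin gene, rose at least 31.6-fold (adjusted p = 0.0099), Ngp, a neutrophil granule gene, 68.8-fold (adjusted p = 0.0273), and Ifitm6 at least 105-fold (adjusted p = 0.00262). Among the other genes past the threshold with the largest rises were Mmp8, the neutrophil collagenase (at least 6.04-fold, adjusted p = 0.00163), the surface protein gene Cd177 (at least 11.6-fold), the lectin receptor gene Clec4e (at least 6.31-fold), the pattern receptor gene Tlr1 (at least 8-fold), Slfn4 (30.3-fold) and the cytokine gene Il1b (9.68-fold, adjusted p = 0.0391). Over all alternatives the log2 change ran from 5.63 to 6.87 for Ngp and from 4.29 to 5.82 for Slfn4.

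**Figure D1:**
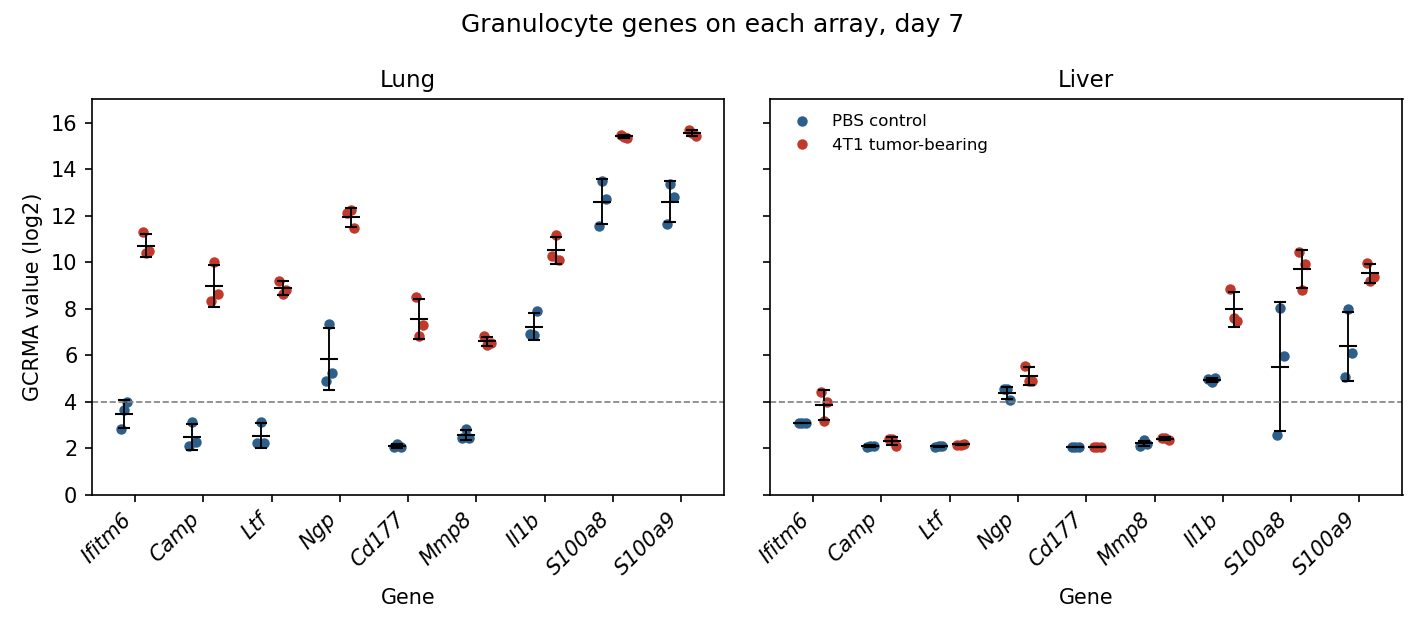
Values of 9 granulocyte and myeloid genes on each array (log2 GCRMA value on the y axis, gene on the x axis), in lung and liver; points are arrays, bars are the mean and SD of 3 arrays, and the dashed line is the filter value of 4. In lung every tumor-bearing array lies above every control array for each gene, while Camp, Ltf, Cd177 and Mmp8 lie under the line on all liver arrays.

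Of the 18 mature neutrophil genes tested in lung, 18 had higher means in tumor-bearing mice. In that list 6 passed over all genes tested and 17 when adjusted over the list alone, and the mean change was 3.32 (log2; camera adjusted p = 9.34e-24, adjusted p = 0.134 with an estimated correlation). The list of immature granulocyte granule genes had 6 tested members. Camp, Ltf and Ngp passed over all genes and 5 members passed adjusted over the list alone, with a mean change of 3.64 (camera adjusted p = 1.57e-07, adjusted p = 0.134 with an estimated correlation). Lcn2, another granule gene, read 13.51 ± 0.45 against 12.84 ± 0.18 and did not pass (adjusted p = 0.328). Erythroid and platelet markers did not pass, with mean changes of -0.15 for erythroid genes (adjusted p = 0.963, the test itself leaning the other way) and -1.02 for platelet genes (adjusted p = 0.29). Without tumor replicate 2 the platelet list passed as lower (mean change -1.98, adjusted p = 0.000804).

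Several genes tied to the pre-metastatic niche missed the threshold over all genes in lung, although their arrays did not overlap between groups. S100a8 and S100a9, the calprotectin subunits, read 15.42 ± 0.07 against 12.60 ± 0.98 (adjusted p = 0.0728) and 15.56 ± 0.11 against 12.60 ± 0.88 (adjusted p = 0.0535). The gelatinase gene Mmp9 read 9.16 ± 1.16 against 5.63 ± 0.11 (adjusted p = 0.0618), Saa3 10.22 ± 1.25 against 8.09 ± 0.86 (adjusted p = 0.295) and the fibronectin gene Fn1 12.15 ± 0.42 against 11.23 ± 0.12 (adjusted p = 0.165). The other probe sets of Mmp9 and Fn1 had larger changes, 5.41 and 2.32, and with all 12 arrays in 1 fit both genes passed. That fit adds no lung arrays but takes the spread of a gene from liver too. There Mmp9 was under the filter and Fn1 had SDs of 0.04 and 0.05. Over all alternatives the adjusted p ran from 0.00201 (without tumor replicate 3) to 0.399 for Mmp9 and from 0.0188 to 0.401 for Fn1. Lox, which codes for lysyl oxidase, read 9.43 ± 0.22 against 9.46 ± 0.22. Prok2, Csf3 and Sele did not pass the filter in lung, and Csf3 and Sele lay at 2.04 on every array. The list of pre-metastatic niche factors, which shares Csf3r, Mmp9, S100a8 and S100a9 with the mature neutrophil list, had a mean change of 0.89 over 24 members (camera adjusted p = 0.000179, adjusted p = 0.223 with an estimated correlation). Its median change was only 0.17, with 16 members higher and 8 lower. None of its members passed over all genes, and 7 passed adjusted over the list alone.

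B cell, interferon and cytokine response lists also shifted up in lung. Of 15 B cell and plasma cell genes measured only 5 passed the filter, and 4 of these 5 had higher means. Over all alternatives the mean change of the list ran from 0.85 to 1.69. Cd79b, part of the B cell receptor, rose 4.46-fold (7.79 ± 0.08 against 5.64 ± 0.08, adjusted p = 0.00163), and 3 members passed adjusted over the list alone (list mean 1.64, camera adjusted p = 9.8e-05, adjusted p = 0.134 with an estimated correlation). The T and NK cell list did not pass (mean change 0.18, adjusted p = 0.675). H2-Eb1, an MHC class II gene, rose 2.09-fold (adjusted p = 0.0391), and 3 of the 7 dendritic cell and MHC class II genes passed adjusted over the list alone (list mean 0.30, camera adjusted p = 0.00393, adjusted p = 0.487 with an estimated correlation). That mean was 0.47 without tumor replicate 1 and 0.18 without tumor replicate 3, and the list means of the arrays overlapped between groups. Of 14 genes of the IL-6 and STAT3 response none passed over all genes and 4 passed adjusted over the list alone (mean change 0.42, camera adjusted p = 9.8e-05, adjusted p = 0.134 with an estimated correlation). Its largest values were those of Socs3, a feedback inhibitor of STAT3 (1.57 ± 0.24 SE, adjusted p = 0.0585), and Junb (0.84 ± 0.13 SE, adjusted p = 0.0585).

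The interferon gamma response list had a mean change of 0.88 in lung, with 22 of 24 members higher and 0 passing, over all genes or adjusted over the list alone (camera adjusted p = 2.28e-06, adjusted p = 0.569 with an estimated correlation). The list mean lay at -0.36, 0.43 and 1.24 from the mean of all lung arrays in tumor-bearing mice and at -0.15, -0.42 and -0.75 in controls, so the groups overlapped, and the mean change was 0.48 without tumor replicate 3. Its largest changes were those of Iigp1 (1.95 ± 0.83 SE) and Cd274 (1.84 ± 0.59 SE), with adjusted p of 0.4 and 0.276. In the type I interferon list 20 of 23 members were higher, 0 passed over all genes and 8 passed adjusted over the list alone (mean change 0.47, camera adjusted p = 4.05e-06, adjusted p = 0.36 with an estimated correlation). Of 35 proliferation genes measured only 13 passed the filter in lung. Of these 13, 11 were higher, 0 passed over all genes and 4 passed adjusted over the list alone (mean change 0.45, camera adjusted p = 0.000765, adjusted p = 0.484 with an estimated correlation). The mean change ran from 0.25 to 0.51 over all alternatives. Mki67 read 6.71 ± 0.56 against 5.03 ± 0.56 and Rrm2 6.78 ± 0.47 against 5.91 ± 0.11 (adjusted p = 0.146 and 0.209).

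Chaperone and stress genes were among those that fell in lung. The co-chaperone genes Dnaja4 and Dnajb2 were 2.58-fold and 1.73-fold lower (adjusted p = 0.019 and 0.0313), the chaperone gene Hspa2 was 1.87-fold lower (adjusted p = 0.0391) and Manf, an endoplasmic reticulum stress gene, 1.71-fold (adjusted p = 0.0467). The others that fell were Mak (at least 1.14-fold), Sec14l2 (2.93-fold), the epithelial transcription factor gene Elf3 (2.8-fold), the glutathione transferase gene Gsta3 (1.55-fold) and Klhl21 (1.54-fold). Of 17 heat shock protein genes 16 were lower, 0 passed over all genes and 11 passed adjusted over the list alone (mean change -0.75, camera adjusted p = 1.2e-08, adjusted p = 0.402 with an estimated correlation). The list mean differed widely among the tumor-bearing lungs, at -0.79, -0.43 and 0.10 from the mean of all lung arrays, against 0.52, 0.29 and 0.31 in the controls.

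Of 22 genes of the unfolded protein response 20 were lower in lung, with Manf passing over all genes and 7 adjusted over the list alone (mean change -0.32, camera adjusted p = 3.46e-07, adjusted p = 0.145 with an estimated correlation). Of 13 targets of NRF2, the regulator of oxidative stress genes, 12 were lower, 0 passed over all genes and 5 passed adjusted over the list alone (mean change -0.35, camera adjusted p = 6.77e-05, adjusted p = 0.223 with an estimated correlation). Hmox1 read 7.20 ± 0.41 against 8.06 ± 0.08 and Aox1 9.55 ± 0.28 against 10.39 ± 0.17. Alveolar epithelium and endothelial genes did not pass (mean changes 0.02 and -0.01, adjusted p = 0.934 and 0.903), and for the endothelial list the mean and the test differed in sign. Cardiac muscle genes varied among arrays of both groups, their mean being 5.73, 8.78 and 8.42 in tumor-bearing and 4.45, 9.07 and 9.85 in control lungs (list adjusted p = 0.963). That list passed as lower without control replicate 1 (mean change -1.82, adjusted p = 0.00132).

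In total 49 genes were higher and 9 lower in the lungs of tumor-bearing mice at an adjusted p under 0.05, of 7907 tested (limma). At an unadjusted p under 0.05 there were 1042 genes, where 395 would be expected by chance. In all 58 the arrays of the groups did not overlap, which held for 18.6% of the genes tested against 10% by chance. With 1 array left out, 21, 27 and 33 genes passed without tumor replicates 1, 2 and 3, and 5, 14 and 5 without control replicates 1, 2 and 3. Without both arrays rich in hepatocyte transcripts, a choice made after seeing the data, 0 genes passed in limma and 769 had an unadjusted p under 0.05.

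Of the 44 lists tested in lung, 13 passed as higher and 5 as lower, and 0 passed with an estimated correlation. A directional test of each list by itself (fry) passed 8 of the 18: mature neutrophil, immature granulocyte, IL-6 and STAT3 response, B cell, pre-metastatic niche, NF-kappa-B and cytokine, unfolded protein response and NRF2 targets. The camera call of 6 lists ended when 1 array was left out. They included monocyte and macrophage (mean 0.25, adjusted p = 0.00642, and 0.0699 without tumor replicate 1), NF-kappa-B and cytokines (mean 0.45, adjusted p = 0.00304, and 0.0591 without tumor replicate 1) and airway epithelium (mean -0.50, adjusted p = 0.01, and 0.251 and 0.0937 without tumor replicate 3 and control replicate 3). The cholesterol synthesis call (mean -0.27, adjusted p = 0.0195) ended without tumor replicate 3 (0.323) or control replicate 1 (0.0667). The immediate early gene call (mean 0.33, adjusted p = 0.0195) ended without tumor replicate 1 (0.0642, mean 0.14), tumor replicate 2 (0.353) or control replicate 3 (0.0649), and the mean was 0.55 without tumor replicate 3. The extracellular matrix call (mean 0.18, adjusted p = 0.0203) ended without tumor replicate 1 (0.188), tumor replicate 3 (0.158), control replicate 1 (0.0805) or control replicate 3 (0.183), and the mean ran from 0.07 without tumor replicate 1 to 0.32 without tumor replicate 2, being 0.27 without control replicate 2. Their adjusted p with an estimated correlation ran from 0.218 for monocytes and macrophages and 0.268 for NF-kappa-B to 0.487 for airway epithelium, 0.642 for cholesterol synthesis and for immediate early genes, and 0.786 for extracellular matrix. Among these 6 lists only the NF-kappa-B list had array means that did not overlap between groups. The lower lists numbered 8 without tumor replicate 1, tumor replicate 2 or control replicate 1, and 3 without tumor replicate 3. Without both arrays rich in hepatocyte transcripts 10 lists passed as higher and 7 as lower.

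**Figure D2:**
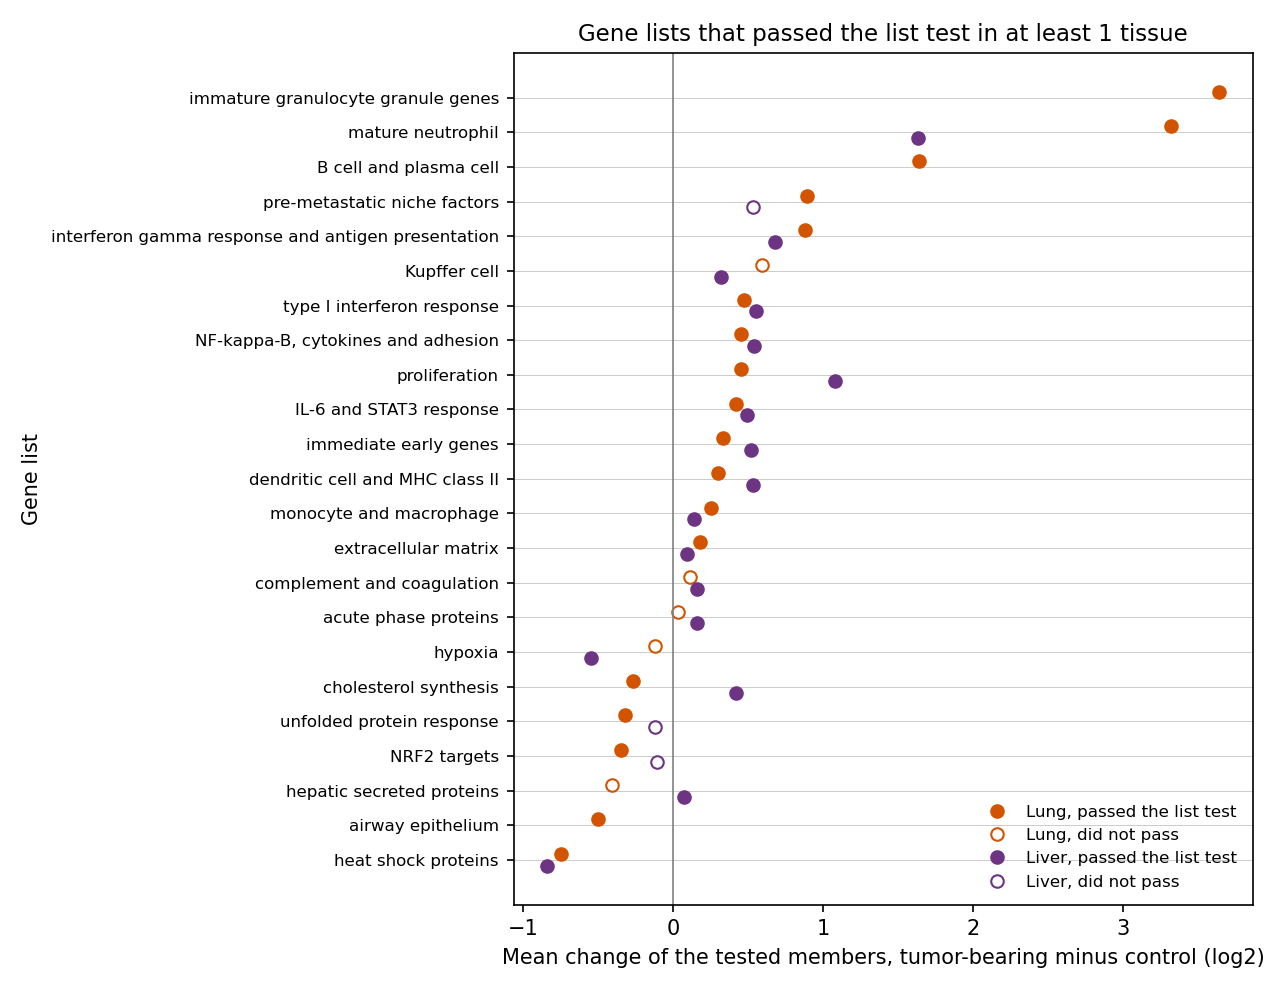
Mean change of the tested members of each list that passed the camera test in lung or liver (x axis, tumor-bearing minus control, log2; list on the y axis); filled points passed at an adjusted p under 0.05, open points did not, and a missing point marks a list with too few members tested. The granulocyte lists lie farthest to the right in lung, at 3.64 and 3.32, and the heat shock protein list lies lowest in both tissues, at -0.75 in lung and -0.84 in liver.

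In liver, Il1b, Il1rn, Socs3, Myc and Il6st were among the genes that rose in tumor-bearing mice. Il1b rose 8.19-fold (7.97 ± 0.75 against 4.94 ± 0.08, SD, n = 3 each, limma adjusted p = 0.0348), and Il1rn, the gene of the antagonist of its receptor, 3.96-fold (adjusted p = 0.0338). Socs3 rose 3.3-fold (11.42 ± 0.20 against 9.70 ± 0.07, adjusted p = 0.0323), Myc 3.29-fold (adjusted p = 0.0323) and Il6st, the signalling receptor subunit of IL-6, 1.51-fold (adjusted p = 0.0484). Other large rises were those of Cda, the cytidine deaminase gene (at least 8.82-fold, adjusted p = 0.0323), Lnx1 (4.56-fold), the activin subunit gene Inhba (4.43-fold), the condensin gene Ncapg2 (at least 1.41-fold), the interferon-inducible gene Gbp6 (4.09-fold), the matrix protein gene Mgp (3.73-fold) and Niban2 (3.73-fold).

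Among genes past the threshold, the largest falls in liver were those of Nr0b2, which codes for a repressor of bile acid synthesis genes (9.16 ± 0.64 against 11.36 ± 0.24, 4.62-fold lower, adjusted p = 0.0478), and of the oxygen-sensing hydroxylase gene Egln3 (3.87-fold lower, adjusted p = 0.0419). Over all alternatives the log2 change of Egln3 ran from -2.18 to -0.97. Tmprss2 was 3.69-fold lower (adjusted p = 0.0338), but its other probe set changed by -0.05. The transferrin receptor gene Tfrc was 3.19-fold lower (adjusted p = 0.0419), Car1, a carbonic anhydrase gene of erythroid cells, 3.49-fold (adjusted p = 0.0484), and Lmo4 3.15-fold. Polr1b, an RNA polymerase I subunit gene, read 3.78 ± 0.25 against 5.17 ± 0.13, with 2 of the 3 tumor arrays under the filter. Rce1, Gpsm1 and Rgs1 were at least 1.85-fold, 1.53-fold and 1.63-fold lower. The co-chaperone gene Dnajb2 was 1.8-fold lower (adjusted p = 0.0419).

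The IL-6 and STAT3 response list shifted up in liver, with 13 of 16 members higher. Socs3, Myc and Il6st passed over all genes, and 8 members were higher and 1 lower when adjusted over the list alone (mean change 0.49, camera adjusted p = 2.76e-05, adjusted p = 0.396 with an estimated correlation). In the interferon gamma list 24 of 25 members were higher and Gbp6 passed, over all genes and adjusted over the list alone (mean change 0.68, camera adjusted p = 1.22e-07, adjusted p = 0.443 with an estimated correlation). Its list mean lay at -0.02, 0.30 and 0.73 from the mean of all liver arrays in tumor-bearing mice and at 0.02, -0.36 and -0.67 in controls, so the groups overlapped. In the type I interferon list 24 of 25 were higher, 0 passed over all genes and 3 passed adjusted over the list alone (mean change 0.55, camera adjusted p = 6.29e-07, adjusted p = 0.396 with an estimated correlation). Dhx58 and Ifit1 changed most in it (1.24 ± 0.23 and 1.23 ± 0.35 SE, adjusted p = 0.0591 and 0.106).

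Of 35 proliferation genes measured only 13 passed the filter in liver, and 12 of these 13 were higher. Their mean change was 1.08 (camera adjusted p = 9.08e-06, adjusted p = 0.443 with an estimated correlation). Over all genes 0 passed, and 4 passed adjusted over the list alone. The mean change ran from 0.63 to 1.32 over all alternatives. The list mean lay at 0.30, 0.05 and 1.27 from the mean of all liver arrays in tumor-bearing mice 1, 2 and 3, against -0.46, -0.73 and -0.43 in controls, so tumor replicate 3 stood apart. The replication licensing genes Mcm5 and Mcm6 read 6.19 ± 2.11 against 3.75 ± 0.42 and 9.65 ± 0.75 against 7.89 ± 0.57 (adjusted p = 0.209 and 0.0971). Of 18 cholesterol synthesis genes 15 were higher, 0 passed over all genes and 4 passed adjusted over the list alone (mean change 0.42, camera adjusted p = 9.08e-06, adjusted p = 0.443 with an estimated correlation). Its list mean lay at -0.03, 0.35 and 0.31 in tumor-bearing mice and at 0.01, -0.50 and -0.14 in controls, so the groups overlapped here too. Mvk, the mevalonate kinase gene, changed by 1.11 ± 0.21 and Hmgcs1 by 0.90 ± 0.17 (SE, adjusted p = 0.0587 and 0.0585). Complement and coagulation genes shifted slightly, with 22 of 27 higher and 0 passing over all genes or adjusted over the list alone (mean change 0.16, camera adjusted p = 0.0004, adjusted p = 0.321 with an estimated correlation). Immediate early genes were higher in 15 of 17 cases, 0 passing over all genes and 3 adjusted over the list alone (mean change 0.52, camera adjusted p = 0.000455, adjusted p = 0.321 with an estimated correlation), and Egr1 read 7.94 ± 1.29 against 6.02 ± 0.15. The Kupffer cell list, markers of the macrophages of the liver, had a mean change of 0.32, with 0 passing over all genes and 1 adjusted over the list alone (camera adjusted p = 0.00259, adjusted p = 0.396 with an estimated correlation), and 0.21 without tumor replicate 3.

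Heat shock protein genes were lower in liver too, in 17 of 17 cases, with 0 passing over all genes and 6 adjusted over the list alone (mean change -0.84, camera adjusted p = 0.00138, adjusted p = 0.489 with an estimated correlation). Hspb1 read 4.31 ± 0.50 against 7.21 ± 1.07 and Hsph1 10.55 ± 1.14 against 12.24 ± 0.29 (adjusted p = 0.0616 and 0.142). The list mean lay at -0.99, -0.37 and 0.10 from the mean of all liver arrays in tumor-bearing mice 1, 2 and 3 and at 0.73, 0.29 and 0.24 in the controls. Of the 15 hypoxia genes 13 were lower, Egln3 passing over all genes and 7 lower and 1 higher adjusted over the list alone (mean change -0.55, camera adjusted p = 0.0298, adjusted p = 0.396 with an estimated correlation), and the call ended without control replicate 2 (adjusted p = 0.0608).

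**Figure D3:**
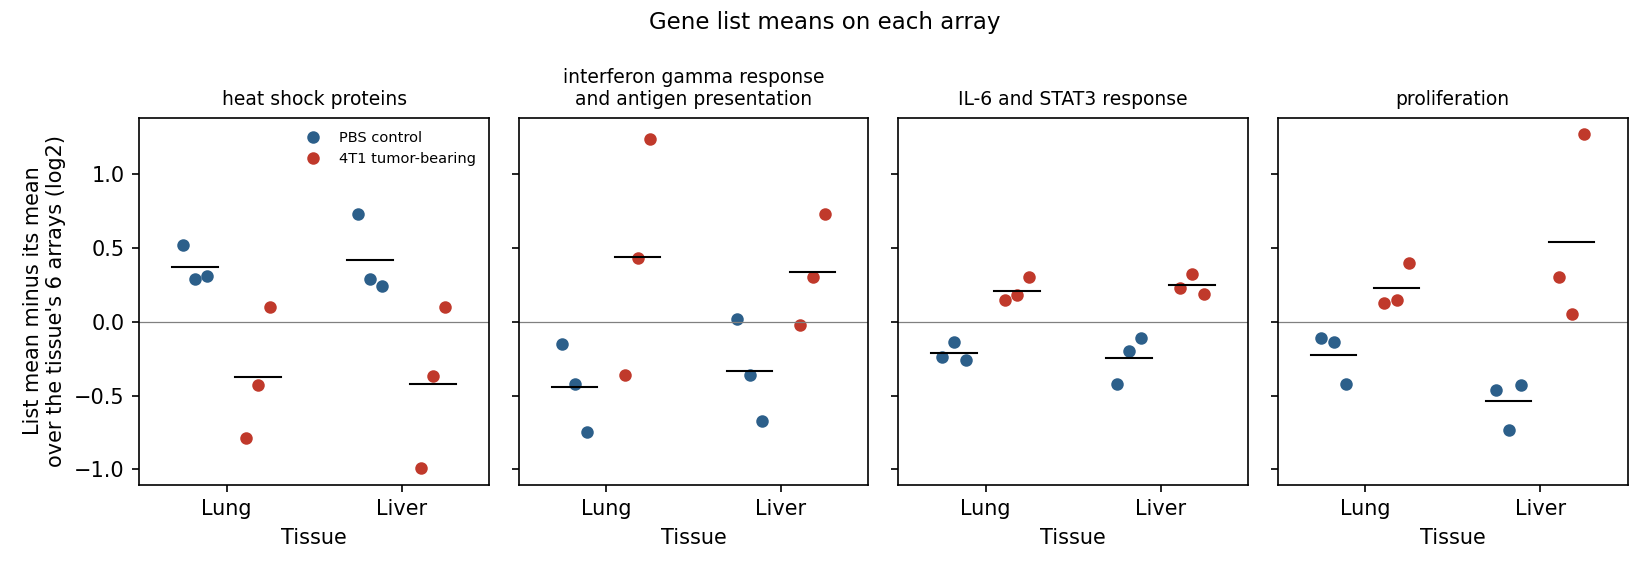
Mean of 4 gene lists on each array, as the difference from the list's mean over the 6 arrays of the tissue (y axis, log2; tissue on the x axis); points are arrays, from left to right replicates 1 to 3, and lines are group means. In the heat shock list the tumor-bearing arrays run from -0.79 to 0.10 in lung and from -0.99 to 0.10 in liver, and all lie below the controls.

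Neutrophil genes in liver were mostly under the filter, and 6 members of the mature neutrophil list were tested. Of these 5 were higher, Il1b passed over all genes, and 3 were higher and 1 lower adjusted over the list alone (mean change 1.63, camera adjusted p = 0.0298, adjusted p = 0.396 with an estimated correlation). The call ended without tumor replicate 2 (adjusted p = 0.108), tumor replicate 3 (0.059) or control replicate 3 (0.0702). S100a8 and S100a9 read 9.72 ± 0.83 against 5.51 ± 2.76 and 9.51 ± 0.40 against 6.38 ± 1.47 (adjusted p = 0.138 and 0.0817). Lcn2, Saa3 and Fn1 changed by 0.11, -0.25 and 0.15 (adjusted p = 0.833, 0.608 and 0.221), and Mmp9, Lox, Prok2, Csf3 and Sele were not tested, being under the filter.

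In total 49 genes were higher and 95 lower in the livers of tumor-bearing mice, of 7712 tested (limma), and 1997 genes had an unadjusted p under 0.05 where 386 would be expected. The arrays did not overlap for any of the 144 genes, as for 33.1% of the genes tested against 10% by chance. Leaving out tumor replicate 1 left 1 gene past the threshold, and leaving out any of the other 5 arrays left 0, with 1456 to 1952 genes at an unadjusted p under 0.05. The median change of all genes was -0.066 as deposited, -0.006 after a further quantile normalization and 0.053 after median centring, and the split of higher and lower genes moved with it, from 49 and 95 (34% higher) to 46 and 41 (52.9%) and 119 and 73 (62%). After the quantile normalization 82 of the 144 genes still passed, and Nr0b2, Car1, Rgs1 and Dnajb2 were among those that no longer did.

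Of the 37 lists tested in liver, 15 passed as higher and 2 as lower, and 0 passed with an estimated correlation. The fry test passed the IL-6 and STAT3, complement, immediate early and hypoxia lists. Apart from the hypoxia and mature neutrophil lists, 6 lists lost their camera call when 1 array was left out. The acute phase call (mean 0.16, adjusted p = 0.00147) ended without control replicate 1 (0.1, mean 0.03), its mean being 0.27 without control replicate 2, and the NF-kappa-B call (mean 0.54, adjusted p = 0.0298) without tumor replicate 2 (0.0644) or control replicate 3 (0.105). The extracellular matrix call (mean 0.09, adjusted p = 0.009) ended without tumor replicate 3 (0.0647, mean 0.02) or control replicate 2 (0.0608, mean 0.01), its mean being 0.14 without tumor replicate 2 and 0.21 without control replicate 1. The hepatic secreted protein call (mean 0.07, adjusted p = 0.0298) ended without tumor replicate 1 (0.0555), tumor replicate 3 (0.0695) or control replicate 2 (0.101). The monocyte and macrophage call (mean 0.14, adjusted p = 0.0426) ended without tumor replicate 2 (0.0562), tumor replicate 3 (0.103), control replicate 1 (0.0916) or control replicate 3 (0.121). The dendritic cell and MHC class II call (mean 0.53, adjusted p = 0.0499) ended without tumor replicate 2 (0.119), tumor replicate 3 (0.173, mean 0.34), control replicate 2 (0.0608) or control replicate 3 (0.0949, mean 0.29), and its mean was 0.86 without tumor replicate 1. With an estimated correlation their adjusted p was 0.489 for acute phase, 0.396 for NF-kappa-B, 0.443 for extracellular matrix and for hepatic secreted proteins, 0.452 for monocytes and macrophages and 0.477 for dendritic cells. After a further quantile normalization 5 of these calls ended: hepatic secreted proteins (adjusted p = 0.39), mature neutrophil (0.081), monocyte and macrophage (0.081), dendritic cell (0.115) and NF-kappa-B (0.053). The array means of the acute phase, extracellular matrix, monocyte and dendritic cell lists overlapped between groups. The lower lists numbered 1 without control replicate 2.

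The tumor effect differed between lung and liver for several granulocyte genes, while for others the difference did not pass. The changes in lung and liver were 2.82 and 4.21 for S100a8 (adjusted p of the difference = 0.697), 2.96 and 3.13 for S100a9 (0.947) and 3.27 and 3.03 for the cytokine gene Il1b (0.877). In the test of the difference itself the change of Ltf was 6.26 ± 0.32 higher in lung than in liver (log2, SE, limma adjusted p = 1.19e-05), that of Mmp8 3.82 ± 0.19 (adjusted p = 1.19e-05), Ifitm6 6.46 ± 0.52 (adjusted p = 0.000565), Cd177 5.45 ± 0.45 (adjusted p = 0.000565) and Clec4e 4.60 ± 0.40 (adjusted p = 0.000623). On the liver arrays Ltf, Cd177, Clec4e and Mmp8 lay under the filter in both groups, and on the lung control arrays these and Ifitm6 did not exceed it, so the sizes rest partly on values near background. With values under 4 set to 4 the differences were 4.88 for Ltf, 2.60 for Mmp8, 6.58 for Ifitm6, 3.54 for Cd177 and 2.66 for Clec4e, a calculation added after seeing the data. In the other direction the change of Cda was -4.58 ± 0.43 in lung relative to liver (adjusted p = 0.000975), with Cda under the filter in lung, and the changes of Mak, Sec14l2, Elf3 and Grpel2 were -1.86, -1.67, -1.44 and -1.15 (adjusted p = 0.000628, 0.00113, 0.00577 and 0.00576), Mak and Elf3 being under the filter in liver. With values under 4 set to 4 the differences of Cda and Mak were -3.14 and -0.19. Of 8433 genes tested the effect was higher in lung for 87 and lower for 44, and 1447 had an unadjusted p under 0.05. Of the 131 genes past the threshold, 28 did not exceed the filter on any liver array and 13 on any lung array. The 131 genes became 82 without liver tumor replicate 1, 64 and 71 without liver control replicates 1 and 2, and 68, 57 and 80 without lung control replicates 1, 2 and 3. Both tissues came from the same mice, and with same-numbered lung and liver arrays of a condition as a fixed block 10 genes lay above and 4 below, against 100 and 49 with a random block.

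Few single genes passed in both tissues. Il1b was higher in both (3.27 ± 0.41 in lung and 3.03 ± 0.37 in liver, log2, SE), where 0.22 genes would be expected from independent lists, and Dnajb2 was lower in both (-0.79 ± 0.09 and -0.85 ± 0.12), where 0.0866 would be expected. No gene passed in opposite directions (0.488 expected, limma). At an unadjusted p under 0.01, 25 genes were higher in both, 19 lower in both and 6 opposite, against 5.67, 9.07 and 17.3 expected. Across the 7194 genes tested in both tissues, which are not independent replicates, the changes correlated at 0.284 (Pearson) and 0.188 (Spearman). Both tissues came from the same mice, so part of this can be shared by mouse: the covariance of the changes was 0.0405, of which 0.0055 would come from deviations shared by same-numbered arrays. Of these 2 shared genes 1 was left without liver tumor replicate 1 and 0 without any other single array.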

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

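The tests of the heat shock, hepatocyte and neutrophil patterns, and the list tests and floored sizes of the difference between tissues, were chosen only after the results were seen, while the splits of the samples and the gene tests of the difference were planned. The test of the difference between tissues picked out 87 genes whose tumor effect was higher in lung than in liver and 44 whose effect was lower (limma). The change in lung minus that in liver was 6.46 for Ifitm6, 6.26 for Ltf, 5.45 for Cd177, 4.60 for Clec4e and 3.82 for Mmp8 (log2). These genes lay at or under the filter in control lung, and all but Ifitm6 also on the liver arrays, and with values under 4 set to 4 the differences were 6.58, 4.88, 3.54, 2.66 and 2.60. It was -1.15 for Grpel2, -1.44 for Elf3, -1.67 for Sec14l2, -1.86 for Mak and -4.58 for Cda, the last 2 becoming -0.19 and -3.14 in that way.

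The same test applied to the lists picked out 8. The mean change in lung minus that in liver was 2.68 for mature neutrophil genes (adjusted p = 9.18e-14, and 0.0528 with an estimated correlation) and 3.03 for immature granulocyte granule genes (adjusted p = 0.000772, and 0.362). In liver only 6 of the 18 mature neutrophil members passed the filter, and too few of the immature list for a test there. Both differences, and their adjusted p, thus rest partly on members near background in liver. The mean change in lung minus that in liver was -0.63 for cholesterol synthesis (adjusted p = 6.2e-07, and 0.547), with means of -0.21 in lung and 0.42 in liver. It was -0.20 for the unfolded protein response (adjusted p = 0.0034, and 0.704), -0.41 for complement and coagulation (adjusted p = 0.0144, and 0.817) and -0.60 for proliferation (adjusted p = 0.0182, and 0.817). Of the 27 complement and coagulation genes only 8 passed the filter in lung, and these had a mean change of 0.11 there, against 0.16 for the list in liver. For growth hormone and sex-biased liver genes it was -0.65 (adjusted p = 0.0334, and 0.362) and for NRF2 targets -0.24 (adjusted p = 0.0334, and 0.703). None of the 8 passed with an estimated correlation, the second p in each pair.

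Probe sets listed with no gene or with several genes stood outside the gene comparisons and also gave calls. In lung 3 were higher and 1 lower of 1019 tested, and in liver 7 were higher and 11 lower of 1021 tested (limma, adjusted over every probe set).

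Of the 10 splits of the 6 arrays of a tissue into groups of 3, the real split gave 58 genes in lung and the highest other 2, and in liver 144 and 1. For the difference between tissues the real split gave 131 genes and the highest other 3. In each comparison 1 split, the real one, gave as many genes, and 10 splits are too few for a share under 0.05.

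Neutrophil transcripts were higher in the lungs of tumor-bearing mice, with a mean change of 3.32 (95% interval 2.61 to 4.03). More blood left in those lungs as the cause of the whole rise is argued against by the erythroid and platelet genes, as far as these track blood. Their mean change was -0.58 (-2.61 to 1.45), an interval that leaves a smaller part open. The 5 erythroid genes among them ran from -1.11 for Alas2 to 0.43 for Car2 and held no globin gene, so they gauge blood only roughly. More neutrophils in the blood of tumor-bearing mice may contribute: the 6 mature neutrophil genes tested in liver had a mean change of 1.63 (0.46 to 2.79). The 18 tested in lung, which include these 6, had a mean of 0.64 in liver (0.23 to 1.04), with Cd177 and Mmp8 at the floor. The second mean is thus not separate support, and the rise in liver rests mostly on the few genes above the filter there. The liver call ended with an estimated correlation (adjusted p = 0.396) and without tumor replicate 2 (0.108), tumor replicate 3 (0.059) or control replicate 3 (0.0702). Blood cells were not measured, and entry of neutrophils into lung tissue stays open as the biological explanation.

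The heat shock protein lists had lower means in tumor-bearing mice in both tissues, calls that ended with an estimated correlation (adjusted p = 0.402 in lung and 0.489 in liver) and with fry (0.0927 and 0.148), no member passing over all genes. The alveolar epithelium and endothelial genes changed by 0.02 (95% interval over arrays -0.22 to 0.26) and -0.01 (-0.26 to 0.25). These values argue against dilution of resident lung cells by leukocytes as large as the mean fall of -0.75 in lung. That fall had a wide interval of its own (-1.49 to -0.01), and its difference from the alveolar genes was -0.77 (-1.71 to 0.18). An equal change of both lists is therefore not excluded, and a smaller dilution stays open. The part of tumor replicate 1 cannot be told apart from the group: without it the mean change was -0.54 in lung (-1.24 to 0.16) and -0.56 in liver (-1.40 to 0.29), the intervals being wide with so few arrays. Time of day or handling at collection could also differ between groups. The correlation of lung and liver changes over 13 clock genes, 0.131 (-0.453 to 0.636, against 0.284 over all genes), left time of day open. Clock genes do not gauge handling, which was not tested and stays open too. The tumor-bearing state stays open beside them.

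Hepatocyte transcripts stood out in lung tumor replicate 1 and lung control replicate 3. Of the 50 genes brightest in liver among those far dimmer in lung, 96% were higher on both arrays than on every other lung array, and 90% with the genes that first showed the pattern left out, a version added after the first. Arrays and genes were both picked on liver transcripts, so these shares decide nothing, and liver RNA carried into these samples stays open. The arrays came from different groups, so the tumor-bearing state cannot account for the pattern on both. The hepatic secreted protein genes averaged 10.92 on control replicate 3 and 10.11 on tumor replicate 1, against 5.26 to 7.10 on the other lung arrays. Their mean change, -0.41 (95% interval -6.44 to 5.61), is too imprecise to settle whether the tumor-bearing state had an added effect.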

How the results depend on the processing

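Leaving out the 2 lung arrays with hepatocyte transcripts, leaving out liver-enriched genes, setting values under 4 to 4 and the list tests between tissues were chosen only after the results were seen. The other alternatives were planned. With 3 arrays in a group the counts moved widely, and the cause was not tested except where fewer arrays or genes were used. Signal near the lowest value limits genes dim in 1 group. Lung counts (49 higher, 9 lower) became 8 and 3 without a filter, 72 and 14 with a filter at 6, 63 and 19 with the mean of probe sets, 55 and 14 after further quantile normalization, 154 and 77 with all 12 arrays in 1 fit, and 80 and 19 with array weights. They were 1 and 0 with the replicate number as a block (limma, 836 at an unadjusted p under 0.05), 0 and 0 without the 2 hepatocyte arrays (769), 119 and 36 at an adjusted p under 0.1, and 40 and 4 with a log2 change of at least 1. Leaving out 1 array gave 4 to 24 higher and 0 to 9 lower. Every probe set, median centring, the eBayes options and leaving out liver-enriched genes stayed within 1.5 times.

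Liver counts (49 higher, 95 lower) became 26 and 36 without a filter, 110 and 241 with a filter at 6, 77 and 122 with every probe set, 46 and 41 after quantile normalization, 119 and 73 with median centring, 96 and 206 with an eBayes trend, 235 and 494 with all 12 arrays, 259 and 569 at an adjusted p under 0.1, and 28 and 23 with a log2 change of at least 1. They were 0 and 0 with the replicate block (limma, 1791 at an unadjusted p under 0.05), and leaving out 1 array gave 0 to 1 higher and 0 lower (1456 to 1952 at an unadjusted p under 0.05). The mean of probe sets, robust eBayes and array weights stayed within 1.5 times. For the difference between tissues (87 above, 44 below) a fixed mouse block gave 10 and 4, a random one 100 and 49, every probe set 117 and 72, and leaving out 1 array 37 to 102 above and 20 to 43 below. Deviations from the group mean of same-numbered lung and liver arrays of a condition correlated at 0.037 to 0.132. Each value lay above those with the other-numbered arrays. Deviations within a group cancel out, so that ordering is partly built in, and this is only a hint that numbers mark mice.

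Genes called in both tissues (2) became 0 without a filter, 44 at an unadjusted p under 0.01, and 0 to 1 with 1 array left out. The correlation of changes (0.284) was 0.192 without a filter and 0.22 to 0.322 with 1 array left out. List counts (lung 13 higher, 5 lower; liver 15 and 2) became 0 and 0 in both tissues with an estimated correlation, and 6 and 2 in lung and 3 and 1 in liver with fry. With 1 array left out they were 9 to 13 and 3 to 8 in lung, and 10 to 14 and 1 to 2 in liver. The lung cardiac muscle list alone turned direction in a call, to 1.84 (adjusted p = 0.0392) without the 2 hepatocyte arrays. Of 1016 values of lists 885 stayed on the same side of the threshold, 108 lost and 22 gained a call, and 42 of the 885 changed sign. For named genes these were 3098, 373 and 129 of 3600, with 19 sign changes among values passing in neither setting, and in the difference between tissues 196 stayed and 3 lost the call of 199. Only lists and genes that passed with all arrays and the chosen settings could lose a call. The shares lost among those are therefore larger than these totals show. In liver, for example, Socs3 lost its call in 7 of 19 alternatives and Car1 in 11 of 19.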

Other observations

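Cirbp and Cyp7a1 are named here by a choice made after their values were seen. Cirbp, a cold-inducible RNA-binding protein gene, was higher in lung (1.55 ± 0.18 SE, limma adjusted p = 0.0299), and its change in liver was 1.44 ± 0.23 (adjusted p = 0.0529). Glucocorticoid target genes did not pass as a list in either tissue (mean changes -0.38 in lung and -0.22 in liver, adjusted p = 0.147 and 0.624, the liver test leaning the other way from its mean). In lung that list passed as lower without tumor replicate 2 (adjusted p = 0.0273) or control replicate 1 (adjusted p = 0.0384). Zbtb16, a glucocorticoid-induced transcription factor gene, read 6.71 ± 2.01 against 10.03 ± 0.23 in liver (SD, n = 3 each, adjusted p = 0.114), and Tsc22d3 changed by -1.08 ± 0.20 (SE, adjusted p = 0.0583).

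In liver, 13 of 17 genes of bile acid synthesis and transport were lower, Nr0b2 passing over all genes and 3 adjusted over the list alone (mean change -0.41, camera adjusted p = 0.197). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, changed by -1.40 ± 0.28 (SE, adjusted p = 0.0642). Chac1, a gene of the unfolded protein response, rose 2.03-fold in liver (adjusted p = 0.0338), while that list did not pass there (mean change -0.12, the test leaning the other way, adjusted p = 0.662). Slc40a1, the iron exporter gene, rose 4.55-fold in lung (adjusted p = 0.0273).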
